A study of Mus musculus with 2 samples.

How the data were processed

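CUT&RUN libraries were made from sorted adipose regulatory T cells with an antibody against HIF-1α or PPAR-γ, 1 library each, and no treatment, per the labels' protocols. No library with a control antibody was used here. Libraries were grouped by the antibody named in their titles. The submitters' processing notes name Bowtie2 2.2.5, SAMtools 1.1, MACS and the build mm10, without their settings. Per the file headers, MACS 2.1.3.3 called peaks on each library separately, with no control file, a q-value limit of 5%, single-end mode, 1 tag kept per position and a regional background window of 10000 bp. The headers also give the human genome size setting of 2.7 Gb for these mouse libraries, which lowers the genome-wide background that a peak is held against; the mouse preset is 1.87 Gb. The protocol in the labels mentions heterologous spike-in DNA, and no scaling by it was used here.

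The deposited pileup is a signal: the coverage of extended tags at the summit after duplicate removal, unscaled between libraries, per the file headers. The deposited −log10 p is that of a Poisson test of the summit against the background of the same library, and the deposited −log10 q is its adjusted form. The deposited fold enrichment is the ratio of pileup to that local background, with the same small constant added to both. The deposited width of each peak is in bp, another unit used as given. These peak values are the authors' own and were used to describe, rank or filter peaks within a list; the pileups also served as counts in the depth-scaled comparisons, and the local background and lowest −log10 p in the expected numbers of missed peaks. A check recomputed the Poisson tail from pileup and fold, and the deposited −log10 p matched within 0.01 for 218 of 218 finite HIF-1α values and 93 of 93 finite PPAR-γ values. The summit tables held the same positions and −log10 q as the peak tables for 219 and 94 peaks.

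Depth per library was taken from the file headers, 9433452 and 3403341 tags before and 5737208 and 2145910 after duplicate removal, with redundant shares of 39.2% and 36.9%. Fragment lengths set by MACS were 284 and 295 bp. Shares have exact Clopper-Pearson intervals at 95%, and a share of 0 is given with its exact upper limit and the share that 3 counts would be. Amplified reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

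Shared peaks were counted by an overlap of at least 1 bp and compared with 10000 random placements of the second list on the same sequences, ending at the last peak of either list. Summit positions were compared with 10000 placements between the outermost annotated or called positions of each chromosome. Shares of summits by gene context were compared with placements (two-sided) and between the lists by Fisher's exact test (two-sided), and gene lists with placements (one-sided), each with Benjamini-Hochberg adjustment. Such placements amount to a permutation test of positions, and the smallest p they can give is 1e-04. The comparisons, the 10 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Changes that the gene table made necessary are given below. Named genes were those linked to the 15 peaks of each list with the highest deposited p on chromosomes, those linked to the 15 shared peaks with the highest smaller −log10 p, and each list gene linked to a peak. A gene was linked when a summit lay in it or within 10 kb; otherwise the nearest protein-coding gene is given with its distance. All listed genes matched the gene table, 1 of them by an older symbol.

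Gene positions came from a RefSeq gene table of the GRCm38.p6 assembly, the same assembly as mm10. It gives gene starts and ends without strand, exons or sequence. The promoter class set out in advance was therefore replaced by distance to either gene end, within 1 kb, and exon and intron classes by gene body. Gene links and nearest genes, set out in advance by distance to the transcription start, were likewise measured from either gene end. Motif content and soft-masked repeats needed genome sequence and were not analysed here. No list of known high-signal regions was used here.

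Depth-scaled pileup ratios of shared pairs were tested by an exact conditional binomial test against the ratio of remaining tags. Peaks of a single list were set against equal density per tag. The tags a call needed in the other library came from the local background in the peak's own library, scaled by depth. The limit of a call was the lowest deposited −log10 p of the other library. These comparisons, the T cell receptor β test, the 3.0 to 3.5 Mb count and the comparison of shared with unshared HIF-1α summits were chosen after seeing the data. The expected number of peaks missed through depth was computed in 3 versions, revised after earlier values had been seen: with counting error of the shallower library only, with pileups corrected for selection by calling, and with counting error of both libraries. The closing section gives each version over the whole of both lists.

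The procedures were tested on simulated data. For shared peaks, 20 of 20 overlaps placed among 85 peaks were found, and 0% of 100 pairs of random lists had p under 0.05. For gene lists, 10 summits moved onto list genes among 192 were all recovered, with 11 genes linked, and 1% of random summit sets had p under 0.05. For pair ratios, 89 pairs were drawn from HIF-1α pileups, of shared peaks or not, with counting error only. Of pairs changed 3-fold, 82.4% were recovered, and 0.754% of unchanged pairs were called. The simulation had no limit of 1 tag per position and required no PPAR-γ call. Its rates therefore do not carry over to the observed pairs. Alternatives covered stricter peak thresholds, the overlap rule, list length, link distance, the genome size setting and the sequences included. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.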

Results

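Regulatory T cells of mouse adipose tissue were profiled by CUT&RUN, an assay in which an antibody guides protein A-fused micrococcal nuclease to its target in permeabilised cells and the released DNA fragments are sequenced. The cells were sorted from the adipose tissue of 4-month-old male mice that carry a Foxp3-linked Cre and a YFP reporter, with about 30000 cells per assay. One assay used an antibody against HIF-1α, the oxygen-regulated subunit of a transcription factor that induces glycolytic genes, and the other an antibody against PPAR-γ, a nuclear receptor for lipids. Each antibody had 1 library, so no difference between the antibodies has a replicate check, and every test compares these 2 libraries or lists, not the antibodies. The HIF-1α library held 9433452 tags, of which 5737208 remained after duplicates were removed, and the PPAR-γ library held 3403341 and 2145910. The ratio of remaining tags was 2.67. Intervals are 95% exact intervals and cover counting error only.

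The HIF-1α list held 219 peaks and the PPAR-γ list 94. In both lists the peak with the highest deposited −log10 p lay on chromosome 9 at Gm33838 and 29.5 kb from Rpusd4, with values of 380.0 (HIF-1α, positions 35305135 to 35305717) and 358 (PPAR-γ, 35305108 to 35305720). The next was inside Chl1, a neural cell adhesion gene, on chromosome 6 (103648922 to 103649480 in the PPAR-γ list), at 267 and 266. Most of the other leading positions lay far from protein-coding genes. A chromosome 9 cluster from 3000195 to 3038269 held 13 HIF-1α and 9 PPAR-γ peaks, between 297 and 335 kb from Alkbh8. A pair of chromosome 2 peaks, with HIF-1α summits at 98662699 and 98666826, lay 1031 and 1035 kb from Lrrc4c, and a chromosome 12 peak at 3109732 to 3110242 lay 137 kb from Rab10. The leading 15 HIF-1α peaks also included positions nearest to Tcte2, Arid1b, Ly6c2 and Gm2244, and a position inside Cldn34d. Among the leading 15 PPAR-γ peaks were positions inside Lars2, a mitochondrial leucyl-tRNA synthetase gene, and inside the overlapping genes Cmss1 and Filip1l, a position nearest to Pex2, and a position in Rn18s-rs5, a ribosomal RNA-related sequence annotated as a pseudogene, 103 kb from Esp38.

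Peak widths had a median of 401 bp in both lists. The median pileup, the number of extended tags over the summit, was 22 in the HIF-1α list and 25 in the PPAR-γ list, and the authors' median fold enrichment was 8.10 and 9.81. Of the HIF-1α peaks, 27 of 219 (12.3%, interval 8.28 to 17.4) lay on mitochondrial or unplaced sequence, 1 of them mitochondrial. Of the PPAR-γ peaks, 9 of 94 (9.57%, 4.47 to 17.4) did, with 0 mitochondrial peaks (exact upper limit 3.85%; 3 counts would be 3.19%). A further 32 of 192 chromosomal HIF-1α peaks (16.7%, 11.7 to 22.7) and 16 of 85 PPAR-γ peaks (18.8%, 11.2 to 28.8) lay between 3.0 and 3.5 Mb of a chromosome, the stretch where mouse chromosome sequence begins. Random placements put at most 6 and 5 peaks there (permutation of positions, p = 1e-04 each, one-sided, the smallest that the placements can give), a test chosen after the positions were seen.

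Almost the whole PPAR-γ list coincided with the HIF-1α list. Of 94 PPAR-γ peaks, 89 (94.7%, 88.0 to 98.3) overlapped a HIF-1α peak by at least 1 bp, and 89 of 219 HIF-1α peaks (40.6%, 34.1 to 47.5) overlapped a PPAR-γ peak. The leading 15 peaks of each list were all shared; several of them, such as the chromosome 9 cluster, the chromosome 2 pair and the peak nearest to Rab10, lie where mouse sequencing libraries often show high signal whatever the antibody, which was not tested here. Shared positions inside genes included Chl1, Lars2, Mdga2, Atrnl1, Kctd16, Cldn34d, Cdk8, Smo, Acacb, which encodes an acetyl-CoA carboxylase, Ncoa1, which encodes a nuclear receptor coactivator, and Litaf; most of these gene names fall outside the naming rule and were chosen after their values were seen. Some of these were weak, with PPAR-γ and HIF-1α pileups of 10 and 18 at Ncoa1 and of 17 and 16 at Litaf. Other shared positions inside genes were stronger than these, such as Tmem267 (46 and 91), Gm525 (26 and 93) and Aida (24 and 58). Over 10000 random placements of the HIF-1α peaks on the same sequences, the mean number of shared peaks was 0.384 and the highest was 4 (permutation of positions, p = 1e-04, one-sided, the smallest that the placements can give). Summits of overlapping peaks lay a median of 21 bp apart. With the longer list reduced to its leading 94 peaks, 71 of 94 PPAR-γ peaks were shared.

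**Figure D1:**
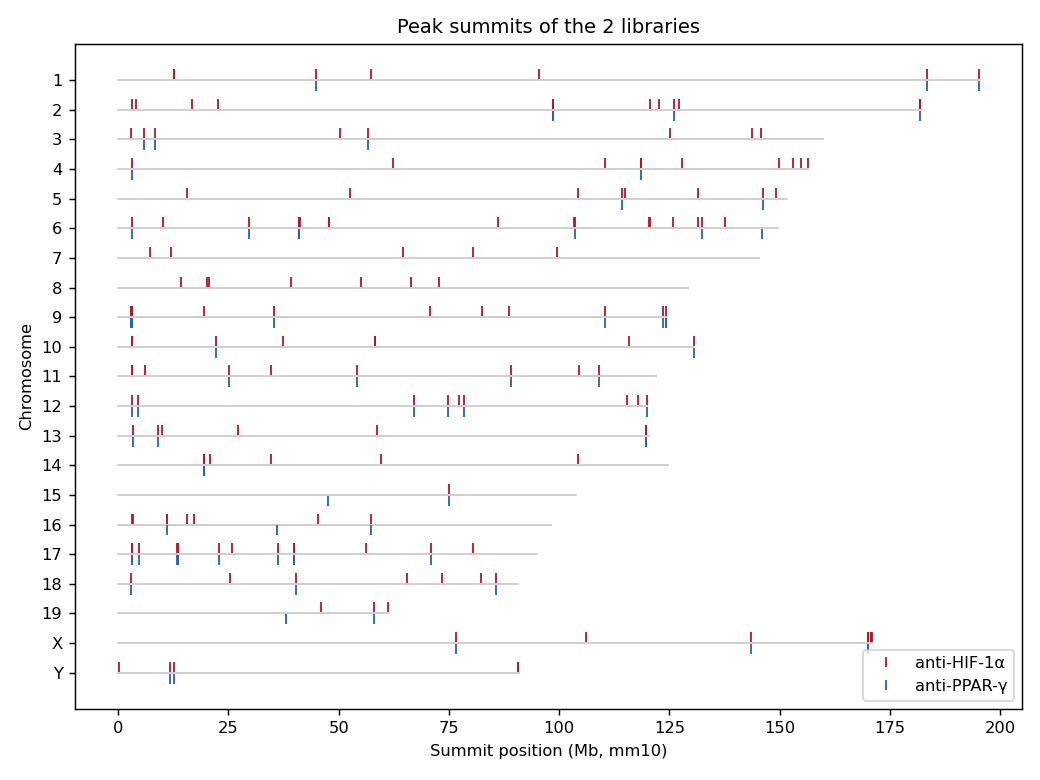
Position of each peak summit in Mb (x axis, mm10) on each chromosome (y axis), with HIF-1α summits as red ticks above the line and PPAR-γ summits as blue ticks below it. Nearly every blue tick has a red tick above it, whereas many red ticks have no blue tick below, as on chromosomes 7 and 8, and several chromosomes show ticks close to their start.

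Among shared positions, tags in proportion to depth were higher in the PPAR-γ library at most leading positions but not at all of them. At Gm33838, near Rpusd4, pileups were 342 in the PPAR-γ and 367 in the HIF-1α library, a depth-scaled ratio of 2.49 (2.14 to 2.89). At Chl1 they were 245 and 247, a ratio of 2.65 (2.21 to 3.18). The position nearest to Pex2 (chromosome 3, 5860202 to 5860750) had pileups of 214 in the PPAR-γ and 100 in the HIF-1α library, a depth-scaled PPAR-γ to HIF-1α ratio of 5.72 (4.49 to 7.33), and the leading position in Rn18s-rs5 had a ratio of 3.64 (3.01 to 4.42). Leading positions nearest to Ly6c2 (1.17, 0.900 to 1.52), Arid1b (0.891, 0.644 to 1.22) and Tcte2 (0.858, 0.665 to 1.098), and the position inside Cldn34d (1.07, 0.765 to 1.48), did not pass the test. At Gphn, which encodes the scaffold protein gephyrin (chromosome 12, 78350820 to 78351168), pileups were 49 and 21, a ratio of 6.24 (3.67 to 11.0). At Lars2 (chromosome 9, 123461793 to 123462265) they were 97 and 55, a ratio of 4.72 (3.35 to 6.69). The highest ratio, 6.98 (3.98 to 12.8), was on chromosome 18 at 85697942 to 85698272, 697 kb from Neto1, and a position at Mir6236 and Gm39429 on chromosome 9 (110281250 to 110281574) had 6.08 (2.88 to 13.7); these and Gphn were picked for their high ratios after the values were seen. Of 89 pairs, 33 were higher in the PPAR-γ library at an adjusted p under 0.05, 1 was lower, at 2700054A10Rik on chromosome 17 (0.643, 0.439 to 0.921), and 55 did not pass (exact conditional binomial test, two-sided, Benjamini-Hochberg over the pairs). The median ratio was 1.55, and it was 1.39 over the 66 pairs with both pileups under 100, of which 16 were called higher. Over the 23 pairs with a pileup of 100 or more the median ratio was 2.12. One tag was kept per position, so pileups could not exceed 568 in the HIF-1α and 590 in the PPAR-γ library, which compresses high values more in the deeper library; weak pairs enter only when the shallower library also reached a peak call.

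**Figure D2:**
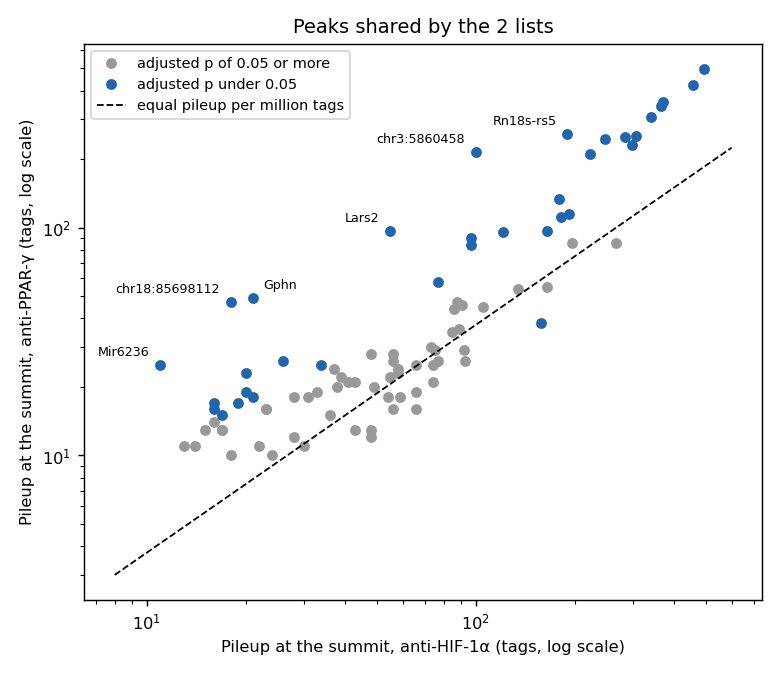
Pileup at the summit in tags for the 89 overlapping pairs, HIF-1α on the x axis and PPAR-γ on the y axis, both log scales. The dashed line marks equal pileup per tag remaining after duplicate removal. Blue points passed an adjusted p under 0.05, and Gphn (21 and 49 tags) and Lars2 (55 and 97 tags) stand well above the line.

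The PPAR-γ list held 5 peaks with no HIF-1α counterpart. They lay inside Myof, a myoferlin gene (chromosome 19, 38023893 to 38024413, pileup 46), 1.58 kb from Kpna1 (chromosome 16, pileup 23), inside Sspn (chromosome 6, pileup 14), 40.5 kb from Csmd3 (chromosome 15, pileup 16) and on an unplaced contig (pileup 17). At equal density per tag the deeper HIF-1α library would have held 123 tags at the Myof summit and 61.5 at the Kpna1 summit, where peak calls needed 16 and 12. These are expectations from depth alone, without the variation between library preparations. The 130 HIF-1α peaks with no PPAR-γ counterpart had a median pileup of 17, against 56 for the shared ones. At equal density these positions would have held a median of 6.36 tags in the PPAR-γ library. A call at the lowest deposited −log10 p of the PPAR-γ list needed a median of 8. The lowest −log10 q of that list was 3.59, against 1.39 in the HIF-1α list, under a q-value limit of 5% in both. A PPAR-γ call may therefore have needed fewer tags. Of the 130 HIF-1α peaks, the highest inside protein-coding genes outside the 3.0 to 3.5 Mb stretch were at Camk2b (pileup 53), Zc3h7a (48), Ano2 (37) and Dpp9 (30).

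HIF-1α summits lay near the ends of protein-coding genes more often than random positions. Of 192 chromosomal summits, 14 (7.29%, 4.04 to 11.9) were within 1 kb of a gene end, against a mean of 3.04% over random placements (permutation of positions, adjusted p = 0.0168, two-sided). They included Pgk1, a glycolytic phosphoglycerate kinase gene (chromosome X, 106186999 to 106187309, 111 bp from the lower-coordinate gene end), Cdc27, a subunit of the anaphase-promoting complex, Hps6, Slc30a4, Elavl4, Oasl1, and the neighbours Tyw5 and Maip1. The rest lay at LOC100504180, Duxf3, Vmn2r29, Gm51572, Asmt, the neighbours Jmjd8 and Stub1, and Lars2. Most of these names fall outside the naming rule and were given after their values were seen. Of the 14, 13 had no PPAR-γ counterpart and 1, Lars2, did. Of 85 PPAR-γ summits, 1 (1.18%, 0.0298 to 6.38) was within 1 kb of a gene end, against a placement mean of 3.02% (same permutation test, adjusted p = 0.633). The shares of the lists were not different after adjustment (Fisher's exact test, p = 0.0433, adjusted p = 0.147). That test treats the lists as independent, although 81 of the 85 chromosomal PPAR-γ peaks were shared and stand on both sides. Among HIF-1α summits, those without a PPAR-γ counterpart had the higher share, 13 of 111 (11.7%) against 1 of 81 (1.23%, odds ratio 10.6, Fisher's exact test, adjusted p = 0.0163, chosen after the lists were seen). Peaks without a counterpart were also weaker, with a median pileup of 17 against 56 for the shared HIF-1α peaks, unplaced sequence included. This contrast therefore cannot be told apart from one of peak strength. The HIF-1α share was no longer past the threshold at a −log10 p of at least 10 (4.97%, permutation p = 0.232) or with gene ends taken within 3 kb (10.4%, p = 0.307). The Pgk1 peak is a weak one, with 10 tags and a −log10 p of 7.13.

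Fewer summits than placed lay inside protein-coding genes, 61 of 192 HIF-1α summits (31.8%, against 39.2%, permutation of positions, adjusted p = 0.0499) and 22 of 85 PPAR-γ summits (25.9%, against 39.4%, adjusted p = 0.0245). Other annotated genes alone held 25 HIF-1α summits (13.0%, against 7.98%, permutation of positions, adjusted p = 0.0432) and 19 PPAR-γ summits (22.4%, against 8.07%, adjusted p = 0.00320). Without unplaced sequence and the 3.0 to 3.5 Mb stretch, the protein-coding shares were 35.6% and 31.9% and neither differed from placements (permutation p = 0.506 and 0.284).

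Of the HIF-1 target genes, 2 of 39 were linked to a HIF-1α peak, Pgk1 and P4ha2, a collagen prolyl hydroxylase gene. The peak at P4ha2 (chromosome 11, 54139945 to 54140718 in the HIF-1α list) lay 8.51 kb outside the gene and was shared, with a pileup of 41 in the HIF-1α and 21 in the PPAR-γ library, a depth-scaled ratio of 1.37 (0.769 to 2.37). Placements linked a mean of 0.161 of these genes (permutation of positions, p = 0.0113, one-sided, adjusted p = 0.226 over all lists of both libraries). In the PPAR-γ list 1 of 39, P4ha2, was linked (permutation p = 0.0618, adjusted p = 0.618). The P4ha2 peak lay past the higher-coordinate gene end in both lists. Without strand it is unknown whether these P4ha2 links meet the rule set out in advance, based on the transcription start. None of the other lists had a linked gene in either library: 0 of 31 PPAR target genes, 0 of 23 adipose Treg genes, 0 of 25 core Treg genes, 0 of 20 T cell identity genes, 0 of 18 macrophage genes, 0 of 14 adipocyte genes, 0 of 12 stromal and endothelial genes, 0 of 9 B and NK cell genes and 0 of 16 housekeeping genes. Placements linked a mean of at most 0.214 genes of any of these lists, so at this number of peaks a lack of linked genes was not distinguishable from random positions. The nearest summit to Slc2a1, a glucose transporter gene, was 560.2 kb away in the HIF-1α list, and the nearest to Pparg was 4.99 Mb away in the HIF-1α and 11.7 Mb away in the PPAR-γ list. For Foxp3 and Il1rl1 the nearest HIF-1α summits were 69.0 Mb and 4.49 Mb away.

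Summits fell on variable segments of the T cell receptor β locus, on chromosome 6 from 40891296 to 41558371, a region singled out after its values were seen. The HIF-1α list had 5 summits there, in Trbv3, Trbv4, Trbv8, Trbv13-1 and Trbv29, and the PPAR-γ list had 4, in Trbv3, Trbv4, Trbv8 and Trbv13-1. The highest pileups were at Trbv8, 34 in the HIF-1α and 25 in the PPAR-γ library. Trbv8 and Trbv29 are annotated as pseudogene segments. Every one of these summits lay inside a segment, 12 to 29 bp from its higher-coordinate end, although the 35 variable segments cover 2.44% of the locus. Random positions in the locus put a mean of 0.114 of 5 and 0.0923 of 4 summits in a segment, and at most 3 and 2 (permutation of positions, p = 1e-04 each, one-sided, the smallest that the placements can give). No summit lay in any other of the 547 annotated variable segments of antigen receptor loci.

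**Figure D3:**
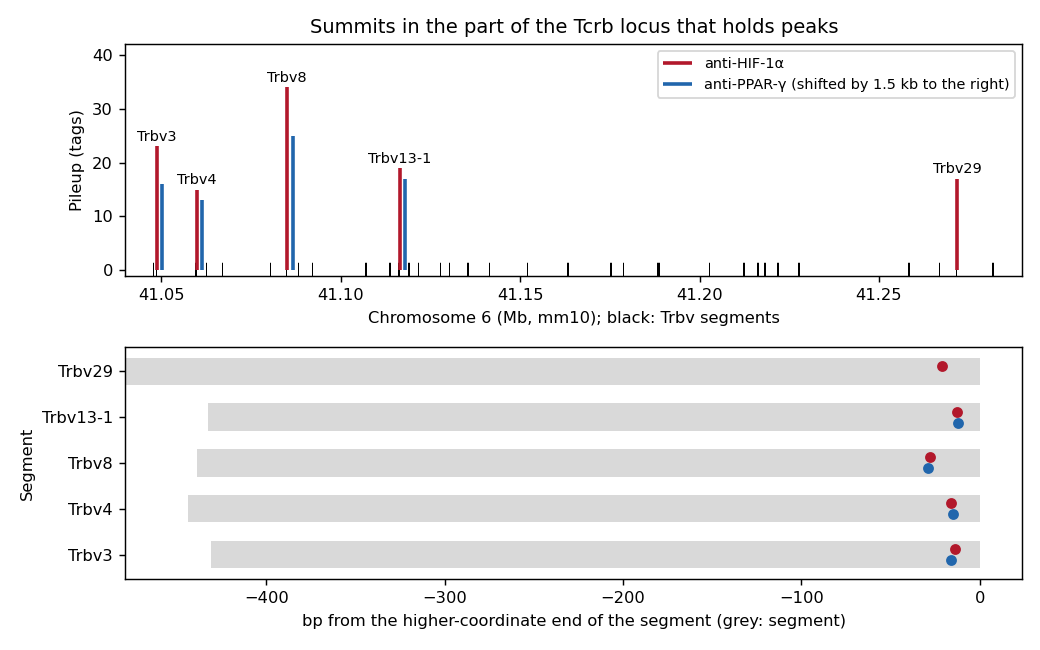
Top, pileup in tags (y axis) at summits along the part of the T cell receptor β locus that holds peaks (x axis, Mb, mm10), with variable segments in black and PPAR-γ lines shifted right for visibility. Bottom, distance in bp from each summit to the higher-coordinate end of its segment (grey bars), red for HIF-1α and blue for PPAR-γ, all within 12 to 29 bp.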

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

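The alternatives that leave out unplaced sequence from the shared peaks, leave out the 3.0 to 3.5 Mb stretch, use the mouse genome size or place peaks between annotated genes were chosen after seeing the data. The number of shared PPAR-γ peaks ranged from 65 to 90 over its alternatives and stayed above every placement in each of them. A fold enrichment of at least 10 left 59 HIF-1α and 44 PPAR-γ peaks, fewer by construction. The share of summits in protein-coding genes was no longer past the threshold without unplaced sequence and the 3.0 to 3.5 Mb stretch, at 35.6% for HIF-1α (permutation p = 0.506) and 31.9% for PPAR-γ (p = 0.284). The HIF-1α share near gene ends was no longer past it at a −log10 p of at least 10 (4.97%, permutation p = 0.232) or within 3 kb (10.4%, p = 0.307). By unadjusted p, HIF-1 target genes linked to HIF-1α peaks were no longer past it within 50 kb (2 genes, permutation p = 0.0642) or at a −log10 p of at least 10 (1 gene, p = 0.125), and in the PPAR-γ list they passed it within 10 kb of a gene end (1 gene, p = 0.0437). The cause was not tested. Of the other alternatives, 21 with a test kept their side of the threshold, 10 gave peak numbers or shares with no test that moved little, and 8 gave 0 linked genes, where p is 1 by construction. Among those without a test, the peak numbers at a q-value limit of 5% could not move, since both lists were called at that limit. Motif, soft-masked repeat and dinucleotide-run alternatives were not run, because no genome sequence was used here. No paired analysis was possible because each antibody had 1 library. The depth of the PPAR-γ library limits how many weak peaks it can show.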

Other observations

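All tests in this part were chosen only after the results they bear on were seen. Almost all PPAR-γ peaks coincide with HIF-1α peaks. Signal that any library gives stays open for the 5 peaks of the PPAR-γ list alone: depth predicts fewer missed peaks of 94 (0.000604, 2.197 and 0.0903 in the 3 versions of the calculation), but this sets 2 single libraries against counting error and uneven preparation could also leave such gaps. Most of the 2.197 came from weak shared PPAR-γ peaks, with summits at 19416246 on chromosome 14 and 3050206 on chromosome 4, not from the 5. Sequence on unplaced contigs or in the 3.0 to 3.5 Mb stretch is not the whole cause, since 65 of 69 PPAR-γ peaks outside it were still shared. For the shared peaks, antibody-independent signal and binding of both factors cannot be told apart: depth-scaled ratios had a median of 1.55 and spread from 0.643 to 6.98, with 33 pairs higher (16 of the 66 with both pileups under 100) and 1 lower past the threshold, a spread that argues against 1 common ratio, but uneven library preparation and the limit of 1 tag per position could also give it and no control library was used here. Joint binding of both factors at these positions is a hypothesis that these libraries left untested.

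The HIF-1α list is longer. Of 80 peaks with a pileup of at least 30, 15 were missed in the PPAR-γ library, against 11.1 expected from the difference in depth (SD 2.31), a gap of 1.70 SD, and of 2.17 SD in both other versions of the calculation. Over all 219 peaks, 130 were missed against 109 expected (SD 5.46), a gap of 3.79 SD, and of 3.32 and 3.09 SD in the other versions. The expected numbers took the −log10 p of the weakest PPAR-γ peak as the limit of a call, so they may be too high. These SDs hold counting error only and each antibody had 1 library, so depth, uneven library preparation and a difference between the antibodies cannot be told apart.

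Summits lie at the ends of Trbv segments. Chance position within the locus is argued against, since 5 of 5 HIF-1α summits lay in segments and random positions gave at most 3. Reads shared between similar segments cannot be told apart from unique signal: 0 summits lay in Trbv13-2 and Trbv13-3, but without sequence it is unknown whether reads there could be placed uniquely. No biological explanation was tested.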
